A study of Mus musculus with 4 samples.

How the data were processed

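Total RNA of limb or back muscle from mouse embryos at E13.5 was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it, per the labels' protocols. The strain is given as BALB/c in the labels. The values the authors deposited are intensities on a linear scale, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The table holds 45101 probe sets, of which 64 are controls. In the deposited columns the 2% trimmed mean was 1478 in WT limb, 1479 in MyoD-null limb, 1478 in WT back and 1477 in the array labelled Myf5-null back, so that each array had already been scaled to one target. The target value, the detection calls and the scanner files were not used here. The column medians were 452, 370, 397 and 491 in that order. After the rescaling described below they were 153, 125, 134 and 166, and 61.4%, 56.0%, 57.9% and 63.6% of probe sets reached 100.

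Groups were taken from the sample titles, 1 array per group. Each array was multiplied to a 2% trimmed mean of 500 over the probe sets that are not controls, signals under 100 were set to 100, and log2 ratios were taken between arrays. Below the floor a signal was treated as having no level, and a ratio against it is given as "at least N-fold". Low genes are compressed by the floor, so their ratios understate a difference. Probe sets were named through the platform annotation supplied with the values, with symbols checked through a RefSeq gene table of GRCm38.p6 by Entrez number. Of 45101 probe sets, 34958 have 1 gene symbol, 932 have several and were not used to name a gene, and 9211 are not listed there and are unnamed here. They stand for 18193 genes, and 0 symbols needed an update. A gene was represented by the probe set with the highest mean log2 signal over the 4 arrays. No genome build belongs to the array values, and no coordinates are given.

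Comparisons were MyoD-null limb over WT limb, the array labelled Myf5-null back over WT back, WT limb over WT back, and the first against the second. With 1 array per group there is no test over samples. A gene was counted at a ratio of 2 or more with the higher array at 200 or more. Gene lists, 41 in all, were written before the data were examined, as were the comparisons, the rule for named genes and the 8 alternatives. Members at 100 or more in at least 1 of the compared arrays entered a list's median. Its percentile among 10000 random lists of the same size, matched on mean log2 signal in 10 bins, describes these arrays and is no p-value. Lists cover myogenic regulators, muscle progenitors, differentiation, sarcomere, fibre types, calcium handling, muscle metabolism, the neuromuscular junction, neurotrophic and guidance factors, muscle-secreted proteins, the Notch pathway and imprinted genes. Further lists hold markers of other cell types, of position along the body, and of technical or general states. Some lists share members, and most slow-fibre and fast-fibre genes are also in the sarcomere list, so the lists are not independent.

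The named genes are the myogenic regulators in every array. Then come the 10 largest and 10 smallest log2 ratios per comparison among genes at 100 or more in both arrays and 200 or more in 1, whose other probe sets at 100 or more in both arrays have the same sign. Next are the 5 largest bounds each way among genes under 100 in one array and at 200 or more in the other, and up to 4 list members with the largest absolute ratio, plus any member needed to describe both directions. Between the limb pair and the back pair they are the 5 largest differences each way and the 5 genes each way with the largest smaller ratio in the same direction, at 100 or more in all 4 arrays. Clone-type names were passed over, except in the lists. The text gives part of the genes this rule yields. Where another probe set of a named gene, at 100 or more in 1 of the arrays, had the opposite sign, this is stated beside the gene. Probe sets under 200 in both arrays with ratios near 0 are not all given.

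The alternatives were no rescaling, quantile normalization, loess of the log ratio on the mean signal with a span of 0.3 within each pair, floors of 50 and 200, a pseudocount of 100 with no floor, the median over all probe sets of a gene, and leaving out probe sets whose names mark probes shared between transcripts or genes. A count was taken to hold when within 1.5 times of the main count. A gene held when it moved by less than the median SD between probe sets of one gene, and a list when it moved by less than the SD of random list medians. Random lists were not drawn again under the alternatives, whose list medians were set against the range of the main random lists. A setting that shrinks ratios can shrink random medians too, so a median inside that range does not show that a call is lost.

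The steps were tested on simulated data. In a copy of each pair with noise drawn from the spread between probe sets, 100 of 18193 genes were given a 4-fold change and 100 a 2.83-fold change. The noise SD was a root mean square over genes, in bins of signal. In the lowest and the highest bin it was 0.58 and 0.43 for the limb pair, 0.56 and 0.37 for the back pair, and 0.57 and 0.43 for limb against back. These values exceed the median SD between probe sets, which was 0.29, 0.25 and 0.31. The changed genes were drawn only from those at 200 or more in the array used as denominator, so dimmer genes were not covered. For the limb pair 98% and 84% of the changed genes were called in the right direction. The shares were 98% and 84% for the back pair, and 97% and 84% for limb against back. Of 200 random unchanged lists, 16, 8 and 9 fell outside the central 95% in the 3 comparisons in that order. A simulated list given a fixed upward shift reached percentiles 99.7, 100 and 95.7, the last within the central 95%. A list within that range is therefore not shown to be unchanged. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.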

Results

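Gene expression was measured in muscle dissected from the limb and from the back of mouse embryos at E13.5. One Affymetrix array was hybridised for each of 4 groups: wild-type limb, MyoD-null limb, wild-type back and Myf5-null back. The series title places the work in the study of how skeletal muscle takes part in the development of motor neurons. MyoD (gene Myod1) and Myf5 are the transcription factors that commit cells to the muscle lineage. Each group had 1 array, so no value below has a replicate error, no p-value was computed, and each difference is between single arrays. The median spread (SD) of the log2 ratio between probe sets of the same gene was 0.29 for the limb pair, 0.25 for the back pair and 0.31 for limb against back, and it covers probe noise, not animals. Signals are scaled intensities with a floor of 100, and a gene was counted when it differed at least 2-fold and reached 200 in the brighter array. The number of arrays limits the precision. The dissected pieces held other tissues besides muscle, with the cartilage gene Col2a1 at 3343 in WT limb and 5495 in WT back. The share of muscle in each piece is not given in the sources used here. Where muscle genes are lower, a smaller share of muscle and a change within muscle cannot be told apart.

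The targeted genes were read first in all 4 arrays. Myod1 had a signal of 1438 in WT limb and 688 in MyoD-null limb (log2 ratio -1.06), and 2870 in WT back and 2333 in the array labelled Myf5-null back (-0.30). A dimmer probe set of Myod1 was also lower in MyoD-null limb, at 92 against 209, but higher in the array labelled Myf5-null back, at 204 against 147. Myf5 was not lower in the array labelled Myf5-null back, where its signal was 583 against 508 in WT back (0.20). In the limb, Myf5 was 1019 in the MyoD-null array against 506 in WT (1.01). The parts of Myod1 and Myf5 that the mutant alleles lack, and the place of the probes in the transcripts, are not given in the sources used here, and a probe outside a deleted part checks nothing. For this reason the fourth array is called the array labelled Myf5-null throughout. Myog, the differentiation factor of the same family, was lower in MyoD-null limb, at 1737 against 2401 (-0.47), and in the array labelled Myf5-null back, at 3404 against 4934 (-0.54). Myf6 stayed under 100 in all 4 arrays.

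**Figure D1:**
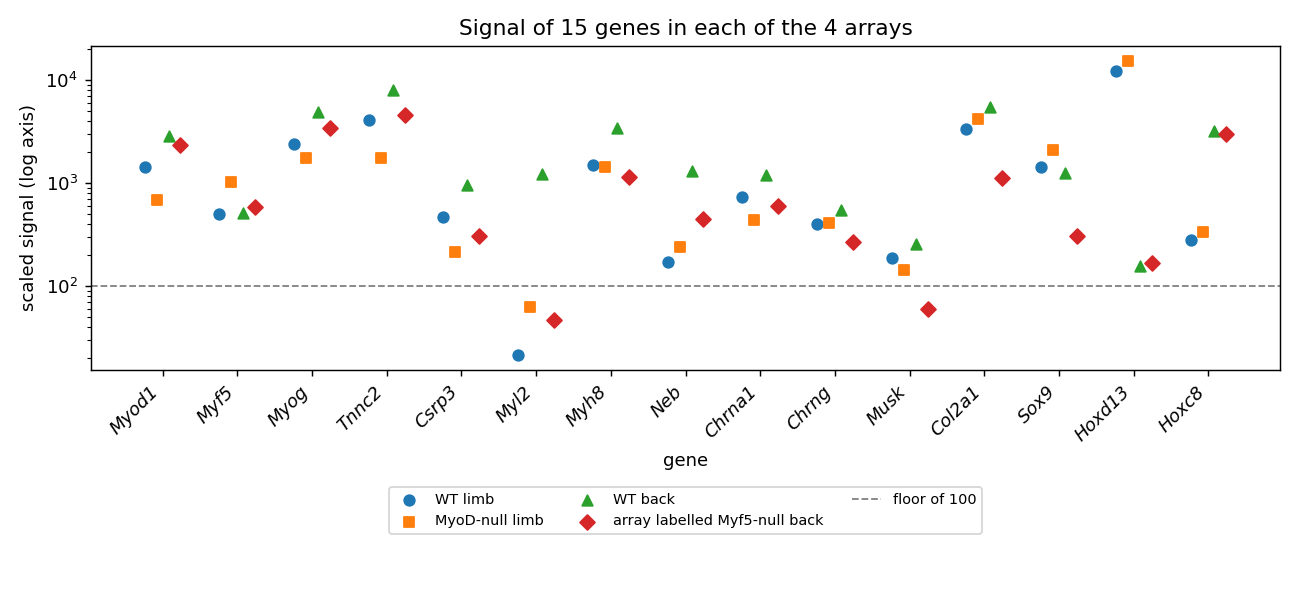
Scaled signal (log axis) of 15 genes in each of the 4 arrays, 1 point per array, with the floor of 100 as a dashed line. Myod1 lies at 688 in MyoD-null limb and 1438 in WT limb, while Myf5 lies at 583 in the array labelled Myf5-null back and 508 in WT back.

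The comparison of MyoD-null with WT limb asked how the piece dissected as limb muscle differs in the mutant. Myod1 itself was lower in that array but stayed above the floor, at 688, so its signal does not show a complete loss, and the genotype is taken from the label. Genes of the contractile apparatus were lower as a group: 34 of the 45 measured sarcomere genes had a log2 ratio below 0, 5 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.38, below all 10000 random lists of matched signal. Myom3, a protein of the sarcomere's M band, was 138 against 335 (-1.28), the fast troponin gene Tnnc2 was 1756 against 4103 (-1.22), and Csrp3, a protein of the Z disc, was 215 against 474 (-1.14). The exception was Myh1, an adult fast myosin heavy chain, at 1256 against 322 (1.96), read by a probe set whose name marks probes shared with related genes. Transcription factors and receptors of muscle progenitors were higher as a group, with 8 of 10 above 0 and a median of 0.46 (percentile 99.8), although none reached 2-fold. Under 2 alternatives the median came within the central 95% of the main random lists, which were not drawn again. It was 0.26 with a floor of 200 and 0.19 when each gene was the median over its probe sets.

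Among the genes of muscle differentiation and fusion the median was -0.51 (percentile 0.05). Klhl41, which stabilises the myofibril, was 851 against 2359 (-1.47), and Cdh15, the cadherin of myoblasts, was 442 against 908 (-1.04). Slow-fibre isoforms had a median of -0.48 (percentile 0.04), with Tnnt1 at 4567 against 9319 (-1.03), and fast-fibre isoforms a median of -0.42 (percentile 1.08), which was -0.16 with a floor of 200, -0.31 under quantile normalization and -0.34 after loess, within the central 95% of the main random lists. Muscle-type energy metabolism had the median -0.62 (percentile 0.14). Of its genes, the muscle creatine kinase Ckm was 169 against 458 (-1.43), while a dimmer probe set of Ckm gave 0.05. Calcium handling at the triad had a median of -0.32 (percentile 4.69), within the central 95% of random lists, and Sln was 239 against 584 (-1.29). The progenitor genes with the largest ratios were Eya1 (665 against 394, 0.76), the HGF receptor Met (731 against 439, 0.73) and Msc (1577 against 959, 0.72). Dimmer probe sets of Eya1 did not follow, with 0.00 and -0.54.

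Genes by which muscle meets the nerve were also read. The postsynaptic list of the neuromuscular junction did not stand apart in MyoD-null limb, with a median of 0.05 (percentile 75.3). Its members went both ways: Dok7, an activator of the receptor kinase MuSK, was 160 against 292 (-0.86) and Chrna1, the alpha subunit of the muscle acetylcholine receptor, 442 against 738 (-0.74), while 9 of 16 members lay above 0. Secreted factors that support neurons had a median of -0.08 (percentile 50.8). Of 23 measured factors, 3 were at least 2-fold lower: Gdnf was 114 against 310 (-1.45), Nrtn 337 against 864 (-1.36), and Lif under 100 against 245, at least 2.45-fold lower. Fgf5 went the other way, at 211 against under 100, at least 2.11-fold higher. Guidance cues had a median of 0.20 (percentile 98.1), with 19 of 29 above 0, but a median of 0, within the central 95% of the main random lists, when each gene was the median over its probe sets. Sema3f was 9587 against 4004 (1.26), but only in a probe set that can share probes with other genes. The other probe sets of Sema3f gave 0.47 and -0.03. Draxin and Sema3e were at least 2.34-fold and 2.32-fold higher, from under 100 in WT limb.

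Lists of other tissues and of general functions were read as well. Each of them outside the central 95% here came within the main random range under at least 1 alternative. Tendon genes had a median of -0.42 (percentile 0.66), which was -0.23 without shared-probe probe sets, within the central 95% of the main random lists. The tendon transcription factor Scx was 218 against 554 (-1.35), with -0.22 in a dimmer probe set. Connective tissue genes had a median of -0.29 (percentile 0.62), within that range at -0.11 as a median over probe sets, -0.18 under quantile normalization and -0.21 after loess, with Tcf21 at 105 against 254 (-1.27), Col1a1 at 8868 against 16300 (-0.88, with -0.26 in another probe set), and Lum in the other direction at 7791 against 3668 (1.09). Red blood cell genes had a median of -0.50 (percentile 0.575), which was -0.24 with a floor of 200 and -0.31 after loess, and respiratory chain genes -0.22 (percentile 0.58), which was -0.06 without shared-probe probe sets, each again within that range. Ribosomal protein genes had a median of -0.26 (percentile 0.61), which turned to 0.074 under quantile normalization, within that range, and to 0.17 without shared-probe probe sets. Cartilage genes had a median of 0.18, within the central 95% of random lists.

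Single genes with the largest ratios in MyoD-null limb came from many functions. Higher were Car3, a carbonic anhydrase of muscle and fat, at 1905 against 311 (2.62), the actin regulator Cap1 at 4297 against 743 (2.53), Crym at 629 against 121 (2.38), Nrip2 at 3813 against 895 (2.09) and the muscle and neuron elongation factor Eef1a2 at 570 against 140 (2.02). A second probe set of Cap1 gave 1.47 and other probe sets of Car3 gave 0.91 and 0.00. Arl2bp was 6689 against 1729 (1.95), with only 0.12 in its second probe set. Lower were Psmd6, a subunit of the proteasome, at 383 against 7477 (-4.29), Grip2 at 167 against 988 (-2.56), Arsk at 116 against 647 (-2.48), the mitochondrial tRNA ligase gene Lars2 at 205 against 1041 (-2.35) and Ubald1 at 116 against 589 (-2.34). A dim probe set of Lars2 gave 0.31. Psmd6 is read by 2 probe sets, and the second gave only -0.16. Of genes under the floor in one array, Cldn34c1 was at least 10.7-fold higher, with 0.35 in another probe set, and Otud3 at least 15.2-fold lower in MyoD-null limb. Eepd1 was at least 5.05-fold lower, but its probe set can share probes, and its other probe set gave 0.80.

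In all, 334 genes were at least 2-fold higher and 753 at least 2-fold lower in MyoD-null limb, so 30.7% of the calls were higher. This split depended on the scaling, since 41.8% were higher after loess and 45.6% after quantile normalization. A simulated unchanged limb pair, with noise SDs of 0.58 at low and 0.43 at high signal, gave 303 genes at least 2-fold higher and 239 lower. This noise is wider than the median spread of 0.29 between probe sets. The simulated counts, here and below, therefore do not show what noise of the median size gives. Of the 41 gene lists, 13 had medians outside the central 95% of random lists, against a nominal 2.05, and 16 of 200 unchanged lists fell outside in the simulated limb pair. Lists share members, muscle lists above all, so such counts, here and below, are not of separate results. Under at least 1 alternative, 8 of the 13 fell within the central 95% of the main random lists. The 2 limb arrays also differed in the 3 prime over 5 prime signal ratio, which was 12.2 in WT limb and 8.06 in MyoD-null limb for Gapdh, and 6.88 and 3.86 for Actb. The spike transcripts added before labelling differed the same way, at 4.23 and 3.06 for dap, 11.2 and 4.90 for lys, and 17.4 and 8.50 for phe. Labelling thus differed together with genotype in this pair. In all 4 arrays the ratios of Gapdh, Actb and these spikes were above 1, with Gapdh from 6.45 in WT back to 12.2 in WT limb. Every array thus leaned to the 3 prime end, which limits the ratios of all comparisons.

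The comparison of the array labelled Myf5-null back with WT back asked the same of the piece dissected as back muscle. Because Myf5 itself was not lower in that array, the directions below rest on its label alone. Contractile genes were lower as a group: 38 of 46 measured sarcomere genes were below 0, 9 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.69, below all 10000 random lists. Cartilage genes were lower by more: 17 of 18 were below 0, 10 were at least 2-fold lower, and the median was -1.29, also below all random lists. Genes of the neuromuscular junction had a median of -0.32 (percentile 0.32), a call lost under some of the alternatives, as given below.

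Of the sarcomere genes, Myl2, the slow and cardiac regulatory light chain, was under 100 against 1226 in WT back, at least 12.3-fold lower. It was under 100 in both limb arrays too, so each of its ratios against WT back rests on that array alone. Csrp3 was 310 against 968 (-1.64), the perinatal myosin Myh8 1145 against 3389 (-1.57) and nebulin, Neb, 452 against 1317 (-1.54). Slow-fibre isoforms had a median of -0.82, with all 9 below 0, and Myh7, the slow myosin heavy chain, was 6640 against 14575 (-1.13). Fast-fibre isoforms had a median of -0.22 (percentile 4.51), within the central 95%, with Tnnt3 at 496 against 1148 (-1.21). Calcium handling at the triad had a median of -0.67, with 14 of 15 below 0, but -0.13 as a median over probe sets, within the central 95% of the main random lists, and Jph1 was 162 against 446 (-1.46). Its exception was Cacnb1 at 339 against 153 (1.15), with -0.62 in a dimmer probe set. Differentiation and fusion genes had a median of -0.41 (percentile 0.02), which was -0.15 with a floor of 200, within the central 95% of the main random lists, with the myosin chaperone Unc45b at 544 against 1835 (-1.75) and the methyltransferase Smyd1 at 360 against 882 (-1.29). Other probe sets of Smyd1 gave 0.26, 0.37 and -0.25. Muscle metabolism had a median of -0.34 (percentile 0.48), within that range at -0.19 as a median over probe sets, and myoglobin, Mb, was under 100 against 372, at least 3.72-fold lower. Progenitor genes had a median of -0.03 (percentile 39.7), and Pax7, the factor of muscle stem cells, was 261 against 681 (-1.38) while Pax3 was 199 against 113 (0.82).

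At the neuromuscular junction, Musk was under 100 against 256, at least 2.56-fold lower. The fetal acetylcholine receptor subunit Chrng was 267 against 544 (-1.03) and Chrna1 was 596 against 1193, while Lama5, a laminin of basement membranes, was 1026 against 569 (0.85), with -0.48 in a dimmer probe set. The median of the list was -0.023 with a floor of 200, -0.15 as a median over probe sets and -0.19 with a pseudocount of 100, within the central 95% of the main random lists. Neurotrophic factors had a median of -0.06 (percentile 15.3), with 2 of 22 at least 2-fold higher: Bdnf at 241 against under 100, at least 2.41-fold, and Ntf5 at 412 against 198 (1.06). Guidance cues had a median of 0.04, with Slit1 at 146 against 324 (-1.15) and Efna1 at 414 against 204 (1.02).

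The cartilage genes included the main collagens of the tissue. Col2a1 was 1119 against 5495 (-2.30), Col9a1 1224 against 5480 (-2.16), Col9a3 992 against 5160 (-2.38), and Col9a2 was under 100 against 582, at least 5.82-fold lower. The transcription factor Sox9 was 304 against 1247 (-2.04) and the link protein gene Hapln1 194 against 723 (-1.90). Further probe sets of Sox9 gave -0.48 (538 against 750) and, near the floor, 0.88, and a dimmer one of Hapln1 gave -0.32. Mia, a protein secreted by cartilage and melanoma cells, was 137 against 645 (-2.23). The trunk list had a median of 0.03, with 12 of 22 above 0, and 2 of its genes were at least 2-fold lower: Pax1 at 157 against 418 (-1.41) and Foxc2 under 100 against 390, at least 3.90-fold lower. Tendon genes had a median of -0.43 (percentile 0.34), which was -0.25 as a median over probe sets, within the central 95% of the main random lists. Tnc was 1750 against 3891 (-1.15), with 0.06 in a probe set near the floor. Connective tissue genes had a median of 0.07. Schwann cell genes had a median of -0.43 (percentile 0.605), within that range at -0.23 with a floor of 200, with Egfl8 at 132 against 455 (-1.79) and Gfra3 at 615 against 285 (1.11).

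Some genes outside muscle and skeleton also separated the back arrays. Afp, made by fetal liver and yolk sac, was 1651 in WT back and under 100 in the array labelled Myf5-null, at least 16.5-fold lower, and Alb was 177 against 609 (-1.78). Of the 8 measured genes of the list of liver and other viscera, these included, 4 were below and 4 above 0, with a median of 0.17. At least 2-fold lower were 3 of them, and 1 was at least 2-fold higher. Ttr was at least 2.15-fold lower, but not with a floor of 50 (0.041). Sftpc, a lung gene and so no reading of liver, was at least 2.27-fold higher. Xist, the RNA of the inactive X chromosome, was 2224 against 8611 (-1.95), and its other probe sets gave -3.08 and a signal under 100 against 502. Of the Y-linked genes, Kdm5d was 205 against 192 (0.09) and Eif2s3y 398 against 362 (0.14). Ribosomal protein genes had a median of 0.31, above all 10000 random lists, which was 0.15 after loess, and 0.043 without shared-probe probe sets and 0.064 under quantile normalization, both within the central 95% of the main random lists.

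Among single genes, Fbxo36 was 1368 against 215 (2.67), the exchange factor gene Kalrn 721 against 118 (2.61), Cdr2l 743 against 137 (2.44), Wnt7a 556 against 113 (2.30) and Lsr 723 against 160 (2.18). Kalrn has 8 probe sets, and the one with the most signal in WT back gave only 0.24, as a second probe set did for Cdr2l, and a dimmer one of Kalrn gave -0.64. A second probe set of Wnt7a gave 0.07. Plekhh3 was at least 6.42-fold higher from under 100 in WT back. Lower were also Anks1 at 117 against 443 (-1.92), Zfp931 at 140 against 524 (-1.90), and Cyp26b1, which breaks down retinoic acid, at least 4.94-fold. In all, 808 genes were at least 2-fold higher and 364 lower, so 68.9% of the calls were higher, against 56.1% after loess and 50.1% after quantile normalization. A simulated unchanged back pair gave 246 higher and 166 lower. Of the 41 lists, 10 lay outside the central 95% of random lists, against a nominal 2.05, and 8 of 200 unchanged lists did in the simulated back pair. Under at least 1 alternative, 7 of the 10 fell within the central 95% of the main random lists. The 3 prime over 5 prime ratio of Gapdh was 6.45 in WT back and 9.46 in the array labelled Myf5-null back, and that of Actb 3.20 and 4.28. Of the spikes added before labelling, phe rose from 4.20 to 5.81 and lys from 2.29 to 2.56, while dap stayed at 1.61 in both.

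**Figure D2:**
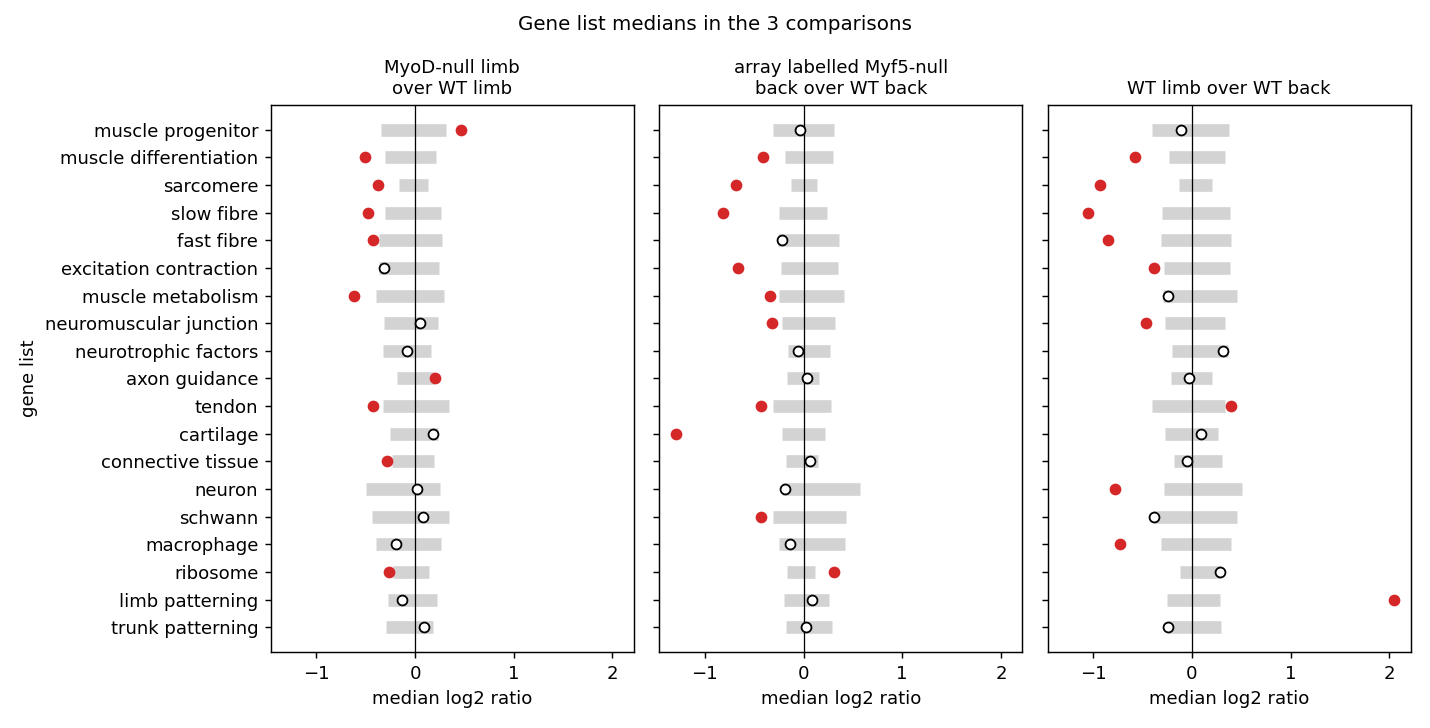
Median log2 ratio of 19 gene lists in the 3 comparisons, 1 point per list. Grey bars span the central 95% of 10000 random lists of matched signal, and filled points lie outside them: sarcomere lies at -0.38, -0.69 and -0.93, cartilage at -1.29 in the array labelled Myf5-null back, and limb patterning at 2.05 in WT limb over WT back.

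The limb pair and the back pair share no array, and region and labelled genotype cannot be told apart. Contractile genes were lower in both, and the cartilage genes only in the array labelled Myf5-null back, a difference between single arrays that was not tested. Of 12426 genes at 200 or more in any array, 30 were at least 2-fold higher in both comparisons, against 21.7 for independent lists, and 32 were lower in both, against 22.1. Opposite calls were also above that number, with 22 against 9.78 higher in MyoD-null limb and lower in the array labelled Myf5-null, and 82 against 49.0 the other way. Across 10911 genes the log2 ratios had Pearson r = -0.16 and Spearman rho = -0.19, and genes are not independent replicates. In both comparisons Csrp3 was lower (-1.14 in limb, -1.64 in back), as were Smtnl2 (-1.28 and -1.40), Esco2, an acetyltransferase of sister chromatid cohesion (-1.41 and -1.27), S100a13 (-1.95 and -1.26) and Upk1a (-1.23 and -1.52). Higher in both were Nxph4 (1.35 and 1.82), Cep97 (1.11 and 1.46), Fut10 (1.05 and 1.06) and Nectin1 (283 against 140 in limb, 349 against 174 in back), and Sema3f (1.26 and 1.17) in its shared-probe probe set alone. Dimmer probe sets went otherwise, with -0.87 in the limb and -0.04 in the back for Fut10, and in the back with 0.06 and -0.44 for Cep97, -0.56 for Nectin1 and -0.11 for Sema3f.

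The log2 ratios differed by 1 or more between the limb pair and the back pair for 1519 of the 10911 genes. The integrin gene Itgb1 was 1599 against 527 in the limb (1.60) and 643 against 1446 in the back (-1.17), while other probe sets of Itgb1 gave 0.77 and -0.38 in the limb, and a dim one 0.50 in the back. Cap1 (2.53 and -0.86), Klhl2 (0.90 and -2.11), Mia (0.72 and -2.23) and Rcor2 (1.91 and -0.87) also had the higher ratio in the limb, but in the back a second probe set of Klhl2 gave 0.49 and one of Cap1 -0.22. Psmd6, Kalrn (-1.31 and 2.61), Fbxo36 (-0.95 and 2.67), Tmc8 (-2.29 and 1.03) and Ubald1 (-2.34 and 0.97) had the higher ratio in the back. In the limb, further probe sets gave 0.18 and 0.78 for Kalrn and 0.26 for Fbxo36. For Psmd6 the difference was -4.12, and it turned to 0.32 without shared-probe probe sets.

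**Figure D3:**
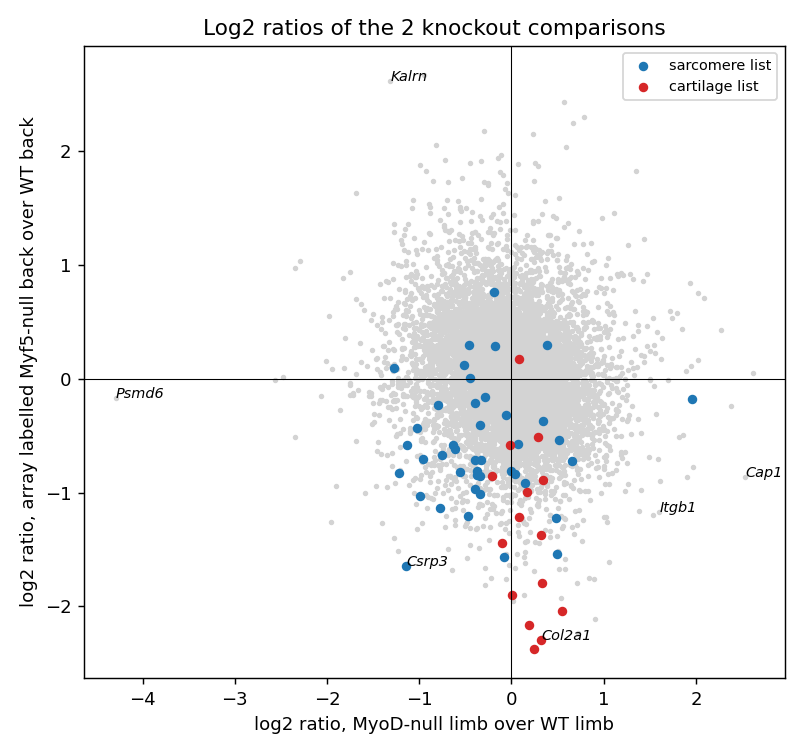
Log2 ratio in MyoD-null limb over WT limb (x axis) against that in the array labelled Myf5-null back over WT back (y axis) for 10911 genes at 100 or more in all 4 arrays, 1 point per gene. Among the sarcomere genes, Csrp3 (-1.14 and -1.64) lies below 0 on both axes and Neb (0.49 and -1.54) on the y axis alone, and cartilage genes such as Col2a1 (0.32 and -2.30) lie below 0 on the y axis alone.

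The comparison of WT limb with WT back described the normal tissues, and it uses the same WT arrays as the limb pair and the back pair. Limb patterning genes were higher in WT limb: 17 of 21 were at least 2-fold higher and 0 lower, with a median of 2.05, above all 10000 random lists. Hoxd13, the Hox gene of the distal limb, was 12104 against 157 (6.27), Msx2 732 against 115 (2.67) and Msx1 2029 against 322 (2.66), while Hoxd10 and Lhx9 were at least 17.6-fold and 11.3-fold higher. Trunk genes were higher in WT back in part: Hoxc8 was 3196 against 279 (-3.52), Zic1 877 against 204 (-2.11) and Hoxa7 at least 9.10-fold, while Tbx18, chosen after its values were seen, was higher in limb at 2901 against 702 (2.05). The trunk list had a median of -0.24 (percentile 2.95). Hoxd13 also separated the other 2 arrays by region, as seen after the fact: it was 15406 in MyoD-null limb and 167 in the array labelled Myf5-null back.

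WT limb had lower signals of muscle genes than WT back. Of 47 sarcomere genes, 18 were at least 2-fold lower in limb and 1 higher, with a median of -0.93, below all random lists. Neb was 172 against 1317 (-2.94), Ldb3 198 against 745 (-1.91, with -0.15 in a dimmer probe set), Lmod3 140 against 528 (-1.92) and Myl2 at least 12.3-fold lower. Slow-fibre isoforms had a median of -1.05 and fast ones -0.85, both below all random lists, as was differentiation and fusion at -0.58. Calcium handling had a median of -0.38 (percentile 0.68), which was -0.09 as a median over probe sets, within the central 95% of the main random lists, and muscle metabolism -0.24 (percentile 4.44). Myod1 (-0.997) and Myog (-1.04) were lower in limb, where the dimmer Myod1 probe set gave 0.51, and Myf5 was 506 against 508. Among progenitor genes (median -0.11, percentile 32.0), Lbx1, the factor of migrating limb muscle precursors, was 447 against 123 (1.87) and Meox2 2613 against 769 (1.76), while Met was 439 against 729 (-0.73).

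The neuromuscular junction list was lower in WT limb, with a median of -0.46 (percentile 0.17). Rapsn, which clusters acetylcholine receptors, was 135 against 428 (-1.67), Chrnb1 332 against 993 (-1.58) and the acetylcholinesterase gene Ache 102 against 216 (-1.08). Neurotrophic factors had a median of 0.32 (percentile 94.9), within the central 95%. Ntf5 was 636 against 198 (1.68) and Gdnf at least 3.10-fold higher in limb, while Fgf7 was 219 against 641 (-1.55, with -0.29 in a dimmer probe set) and Igf1 4404 against 10926 (-1.31). The median of this list was 0.00 with a floor of 200 and 0.12 without shared-probe probe sets. Neuronal genes were lower in limb, with a median of -0.78, below all random lists, which was -0.24 with a floor of 200, within the central 95% of the main random lists, among them Stmn3 (111 against 439, -1.99) and the neurofilament genes Nefm (275 against 898, -1.71) and Nefl (194 against 483, -1.31). Guidance cues had a median of -0.03, with Epha3 at 1293 against 4648 (-1.85).

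In all, 774 genes were at least 2-fold higher and 511 lower in WT limb than in WT back, and 14 of the 41 lists lay outside the central 95% of random lists, against a nominal 2.05, while 9 of 200 unchanged lists did in the simulated pair. Under at least 1 alternative, 6 of the 14 fell within the central 95% of the main random lists. A simulated unchanged pair gave 277 higher and 243 lower. Outside the lists, Mab21l2 was 2105 against 308 (2.77), Gdf5, a factor of joint formation, at least 7.26-fold higher, and Foxd1 at least 8.79-fold lower in limb. Prdm16 was 3123 against 304 (3.36) in 1 probe set, although dimmer ones gave 0.35 and -0.71. Afp, a gene of fetal liver and yolk sac, was 176 against 1651 (-3.23) and Alb 225 against 609 (-1.43), and both were highest in WT back among the 4 arrays. The spike transcripts added before labelling had larger 3 prime over 5 prime ratios in both limb arrays than in both back arrays: for lys they were 11.2 and 4.90 in WT and MyoD-null limb, and 2.29 and 2.56 in WT back and the array labelled Myf5-null back. Labelling does not account for the limb patterning genes, which did not follow these ratios: between the 2 limb arrays, where the lys ratio fell from 11.2 to 4.90, their median was -0.13, and Hoxd13 was 12104 and 15406 against 157 and 167 in the back arrays. For other differences in this comparison, region and labelling cannot be told apart.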

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

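The tests of an array swap, of transcript left by the mutant allele, and of cartilage in the dissected piece, with their criteria, were chosen after their results had been seen, and so were the split of the calls by signal and the reading of cartilage probe sets at 200 or more. Values drew attention where the limb pair and the back pair went in opposite directions. For a list this meant a median outside the central 95% of random lists in both. For a gene it meant being at least 2-fold apart from WT in both and among the 5 largest differences each way named above. Opposite 2-fold calls numbered 22 higher and 82 lower in MyoD-null limb, and the rest of them are not flagged here. These criteria were set with the values in view, each comparison is 1 pair of arrays, and none of the differences was tested. Ribosomal protein genes had a median log2 ratio of -0.26 in MyoD-null limb and 0.31 in the array labelled Myf5-null back. This opposition was absent without shared-probe probe sets (0.17 and 0.043) and under quantile normalization (0.074 and 0.064). The log2 ratio of the limb pair minus that of the back pair was 2.77 for Itgb1, -3.93 for Kalrn and -3.33 for Tmc8. Itgb1 and Kalrn were read by probe sets whose names mark shared probes. As given above, other probe sets of these genes had the opposite sign in the limb and in the back.

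The first pattern is the lopsided count of calls, with 30.7% higher in MyoD-null limb and 68.9% higher in the array labelled Myf5-null back. A brightness trend between paired arrays may account for it: after loess the share was 41.8% in the limb (372 higher and 518 lower) and 56.1% in the back, within the range set beforehand but still uneven, and loess centres the ratios and pulls the share that way in part by construction. By the brighter array's signal, the shares leaned as overall from 200 to 500 (28.5% in the limb and 72.0% in the back) and from 500 to 1000 (33.1% and 59.5%), and only at 1000 or more were they 51.9% in the limb and 37.3% in the back (22 higher and 37 lower). The spike controls added at hybridisation were 1.43 times as bright after scaling in WT limb and 1.49 times in the array labelled Myf5-null back as in WT back, against 0.908 in MyoD-null limb. A real one-way difference of dim genes stays open, since loess would remove it too.

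The second pattern is the lower signal of cartilage genes in the array labelled Myf5-null back, where the tables argue against the brightness trend, since the median was -1.40 after loess and -1.29 before. RNA degradation from the 5 prime end was to be read as the cause if the least lowered probe set of each gene had a median of -0.5 or more, and over 8 genes this planned value was -0.15, on the side that degradation predicts. It was first read that way. It was then read as open, after the same value over 7 genes with probe sets at 200 or more in WT back was seen to be -0.85. Of 15 such probe sets, 14 were below 0. Probe sets near the floor pull the planned value to 0, but choosing probe sets by their WT back signal alone favours ratios below 0. The later value therefore cannot set the planned one aside, and degradation stays undecided. The 3 prime over 5 prime ratios do not decide it: from WT back to the array labelled Myf5-null back they rose from 6.45 to 9.46 for Gapdh and from 3.20 to 4.28 for Actb, but the phe spike, which cannot degrade in the sample, also rose from 4.20 to 5.81 (lys 2.29 to 2.56, dap 1.61 in both), and WT limb, another tissue, had 12.2 and 6.88 and a cartilage median of 0.09 over WT back. Less cartilage in the dissected piece and less cartilage in the embryo cannot be told apart, because 94.4% of the measured cartilage genes were below 0, as either would give, and a change in the mutant embryo stays open as untested.

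The third pattern is Myf5, which was not lower in the array labelled Myf5-null back. A swap of the back arrays, a single wrong label and transcript that the mutant allele still makes cannot be told apart. Neither back array was low in Myf5, at 1.003 times the WT limb signal in WT back and 1.15 times the WT back signal in the array labelled Myf5-null, and the allele and the probe positions are not given in the sources used here.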

How the results depend on the processing

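No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. All alternatives were planned before the values were seen. The deposited scaling moved no result, which says nothing about stability since the arrays were already scaled alike. Over the other alternatives and the deposited scaling together, 859 list medians kept within the spread of random lists, 123 moved beyond it and 2 reversed. Of the gene ratios, 3610 kept within the probe-set spread, 822 moved beyond it and 6 reversed. A sign change was called reversed only where the main list median lay outside the central 95%, or the main gene log2 ratio was at least 1 in size. Other sign changes are among those that kept or moved. For example, the neuromuscular junction median in MyoD-null limb ran from -0.19 to 0.079. Over the alternatives the sarcomere median ran from -0.40 to -0.33 in MyoD-null limb and from -0.98 to -0.86 in WT limb over WT back, and the cartilage median from -1.62 to -0.95 in the array labelled Myf5-null back. Of the lists outside the central 95% of random lists, 8 of 13 in MyoD-null limb, 7 of 10 in the array labelled Myf5-null back and 6 of 14 in WT limb over WT back had a median within the main random range under at least 1 alternative, a count chosen after the values were seen. Those outside it under every alternative were sarcomere and slow-fibre genes in all 3 comparisons, and cartilage in the array labelled Myf5-null back. In MyoD-null limb they were also myogenic regulators, muscle metabolism and differentiation. In WT limb over WT back they were also differentiation, fast-fibre, neuromuscular junction, smooth muscle, macrophage and limb patterning genes. Most slow-fibre and fast-fibre genes are also in the sarcomere list, so these are not separate results. The median of the myogenic regulators in MyoD-null limb is the ratio of Myog alone (-0.47), and the targeted gene Myod1 is among the 3 measured members, so it is not a group result. The cause was not tested, except that a higher floor or a pseudocount shrinks ratios of dim genes by construction, and a median over probe sets includes dim ones. Signal over background limits dim genes most: between 32.3% and 58.3% of the calls in each direction were under the floor in the dimmer array.

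With a floor of 200 the genes at least 2-fold higher and lower numbered 115 and 181 in MyoD-null limb, 152 and 123 in the array labelled Myf5-null back, and 247 and 261 in WT limb over WT back, with 3 higher and 5 lower in both the limb pair and the back pair. With a pseudocount of 100 they were 150 and 329, 413 and 164, 393 and 270, and 7 and 8. As medians over probe sets they were 179 and 429, 492 and 202, 450 and 319, and 11 and 20. Under quantile normalization 518 genes were higher in the array labelled Myf5-null back. Ratios of the limb pair and the back pair differed by 1 or more for 852 genes with the pseudocount and 911 as medians over probe sets.

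The limb patterning median of WT limb over WT back was 1.79 with a floor of 200, 2.19 with a floor of 50, 1.46 over probe sets and 1.75 with the pseudocount, and that of trunk patterning was -0.66 with a floor of 50 and -0.72 without shared-probe probe sets. The neuromuscular junction median was -0.023 with a floor of 200 and -0.15 over probe sets in the array labelled Myf5-null back, and -0.19 over probe sets in MyoD-null limb, where the main value was 0.05. The neurotrophic median of WT limb over WT back was 0 with a floor of 200 and 0.12 without shared-probe probe sets. The sarcomere median in the array labelled Myf5-null back was -0.60 both with a floor of 200 and with the pseudocount.

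Reversed were the ribosome median in MyoD-null limb, at 0.074 under quantile normalization and 0.17 without shared-probe probe sets, and the difference of the limb pair from the back pair of Psmd6 (0.32), the MyoD-null ratios of Eepd1 (0.80) and Sema3f (-0.030), all without shared-probe probe sets. In the array labelled Myf5-null back, Slco2b1 was 0.17 over probe sets, and Ttr was 0.041 with a floor of 50 and 0.018 with the pseudocount.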

Other observations

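Besides muscle, the WT arrays differed in genes of macrophages, the vessel wall and skin. Macrophage genes had a median log2 ratio of -0.72 in WT limb over WT back (percentile 0.01), with Lyve1 at 175 against 1028 (-2.55), the mannose receptor Mrc1 at 520 against 1792 (-1.79) and the complement gene C1qc at 199 against 621 (-1.64). Smooth muscle and pericyte genes had a median of -0.73 (percentile 0.03), with Tagln at 415 against 1476 (-1.83). Epidermal genes had a median of 0.36 (percentile 98.8), within the main random range at 0.18 with a floor of 200, with the basal keratin Krt5 at 5685 against 2454 (1.21), and tendon genes 0.39 (percentile 98.7), with Kera at 1814 against 523 (1.80) and Mkx at 990 against 295 (1.74), although the tendon median was 0.016 without shared-probe probe sets, within that range. Imprinted growth genes had a median of -0.21 (percentile 1.71), within that range at -0.18 with a pseudocount of 100, with Dlk1 at 3455 against 11034 (-1.68). Connective tissue genes had a median of -0.05, but periostin, Postn, was 5509 against 19889 (-1.85) and Prrx2 1612 against 507 (1.67).

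Lists of other cell types lay within the central 95% of random lists in the comparisons given here. The list named liver below also holds genes of other viscera. In MyoD-null limb, the medians were -0.09 for endothelium, -0.04 for smooth muscle, -0.19 for macrophages, 0.02 for neurons, 0.08 for Schwann cells, -0.04 for epidermis, 0.34 for bone, -0.09 for brown fat, -0.85 for pigment cells and -0.78 for liver, these last lists with 6 measured genes each. In the array labelled Myf5-null back they were 0.14 for endothelium, -0.05 for smooth muscle, -0.14 for macrophages, -0.19 for neurons, 0.14 for epidermis, 0.04 for red blood cells, -0.05 for bone, -0.20 for brown fat, 0.56 for pigment cells and 0.17 for liver. In WT limb over WT back they were -0.05 for endothelium, -0.15 for red blood cells, -0.38 for Schwann cells, 0.09 for cartilage, 0.08 for bone, 0.11 for brown fat, 0.63 for pigment cells and -0.32 for liver.

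General states also stayed within that range. For MyoD-null limb, the array labelled Myf5-null back and WT limb over WT back in that order, the medians were 0.11, -0.09 and -0.15 for the cell cycle, -0.04, 0.03 and 0.33 for p53 and cell death, 0.01, 0.01 and 0.00 for immediate early and heat shock genes, and -0.07, 0.12 and 0.11 for hypoxia and glycolysis. They were 0.24, -0.11 and -0.16 for housekeeping genes, 0.00, -0.14 and -0.09 for the Notch pathway, -0.10, 0.06 and -0.01 for muscle-secreted proteins, and -0.56, 0.14 and 0.37 for neural progenitors. Sex-linked genes had 0.10, 0.11 and -0.29, genes beside Myod1 had -0.07, -0.20 and 0.08, and genes beside Myf5 had 0.16, -0.05 and -0.06. Of the remaining lists, imprinted genes had -0.23 in MyoD-null limb and 0.13 in the array labelled Myf5-null back, and respiratory chain genes had 0.08 in the latter and 0.21 in WT limb over WT back. Limb and trunk patterning had -0.13 and 0.09 in MyoD-null limb and 0.09 and 0.03 in the array labelled Myf5-null back, and ribosomal protein genes 0.29 in WT limb over WT back. The myogenic regulators, with 3 of 4 measured, had medians of -0.47, -0.30 and -0.997, of which the first and the last lay outside the range, although the last was -0.24 as a median over probe sets, within it. Each of these main medians is the ratio of 1 gene, Myog in the first and Myod1 in the others.

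Within the trunk list, Hoxc10 was under 100 in MyoD-null limb against 397 in WT limb, at least 3.97-fold lower. Among limb genes, Pitx1, a gene of the hindlimb, was 243 in MyoD-null limb against 757 in WT limb (-1.64), and Tbx4, another, 484 against 815 (-0.75), while Tbx5, a gene of the forelimb, was 1375 against 1152. Tbx5 was chosen after its values were seen, and no explanation of these limb values was tested. Which limbs (fore, hind or both), how many embryos and which sexes went into each array is not given in the sources used here, so the limb pair can differ in limb type, and the back pair, where Xist was 2224 against 8611, in sex, besides the labelled genotype. The 3 measured Y-linked genes lay above 0 in the back pair, but none was at least 2-fold higher, so a difference in sex is not settled.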
